A study of Caenorhabditis elegans with 2 samples.

How the data were processed

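Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed in Caenorhabditis elegans carrying an integrated transgene that expresses NHR-48, a nuclear hormone receptor, with GFP and FLAG at its C terminus. Hermaphrodite larvae of the L4 stage were collected 48.5 h after synchronisation and the tagged protein was precipitated with an antibody against GFP, per the labels. The 2 libraries are labelled as separate biological replicates 1 and 2 of 1 group, and each has its own list of regions. Reads, control libraries and a second condition were not analysed here.

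The authors deposited lists of regions in narrowPeak format on the ce11 and ce10 builds. Per the deposited file listings, each replicate's list and a pooled list of both replicates hold peaks together with background, were called against 1 control file, and served as input for the irreproducible discovery rate (IDR) procedure, which compares the ranks of regions between replicates. The optimal IDR list was derived from the replicate lists and the pooled list, per the same listings. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The signal value of each region is the authors' value on the caller's scale, and it was used only to rank and describe regions within 1 list. The deposited -log10 q value reached its highest value, 3.75, in 82.9% of the IDR peaks on ce11 and was not used for ranking. Each region also carries the authors' summit position. Read counts are not part of these lists, so the sequencing depth of each replicate was unknown and no precision could be derived from it; the number of regions limits the precision instead. Shares are given with exact 95% Clopper-Pearson intervals, which cover counting error only and treat peaks as independent.

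All results were computed on ce11, whose chromosome lengths matched the reference genome, with no region beyond a chromosome end. Gene models came from Ensembl release 115 for the same assembly. IDR peaks on mitochondrial DNA were left out of the comparisons, and the remaining 3338 peaks were called nuclear. A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated 5′ end of a protein-coding transcript, and a peak belonged to it when its summit did. The class of a peak was that of its summit base, in the order coding exon, 5′ UTR, 3′ UTR, exon of a noncoding gene, intron, intergenic. Promoter and class shares were compared with 1000 random placements of the same number of summits within each chromosome, giving a one-sided permutation p for promoters and a two-sided one for classes. Overlap with the replicate lists needed at least 1 bp and was compared with 1000 random placements of the IDR peaks, one-sided. The X share was compared with the length of X, and the share in the central 33.3% of each autosome with that fraction, by two-sided exact binomial tests.

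The 26 gene lists were fixed before the data were examined, and symbols that matched no nuclear protein-coding gene were left out. Each was tested by a two-sided Fisher's exact test of genes with and without an IDR peak summit in the promoter window among 19973 nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the lists. Sequence was taken from 100 bp centred on each summit and from 100 bp centred 300 bp to a randomly chosen side of the same peak. For 9 preset motifs and all 2080 6-mers, counted with their reverse complements, the paired windows were compared by a two-sided exact McNemar test with Benjamini-Hochberg adjustment. Base composition was taken into account by giving the ratio of each preset 6-mer beside the median ratio of 6-mers with the same number of G and C bases. The longer motifs and the AGKKCA pair had no such comparison. The median signal of promoter peaks and other peaks was compared by a two-sided permutation test with 100000 resamples. Peak numbers in 100 kb around nhr-48 and unc-119 were placed among 10000 random windows of the same chromosome, as a description. Genes were named by a rule fixed in advance: the 20 protein-coding genes whose promoter windows held the peaks of highest signal among peaks overlapped in both replicate lists, with 1 gene per peak; nhr-48, unc-119, daf-12 and nhr-8 in any case; and up to 4 genes of each list by signal. The first part of the rule admitted mitochondrial genes, so a ranking of 20 nuclear genes was added after the values were seen.

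Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated regions of the same number, 3361. In 20 sets of randomly placed regions, 1 promoter test and 1 X test fell under 0.05, and 0 of 180 preset motif tests passed adjustment. The regions were placed independently, so these sets cannot show how the promoter, X and motif tests behave where peaks cluster or overlap. The list tests were run on genes drawn at random and not on placed regions, and 2 of 520 passed adjustment. These draws cannot show how the list test behaves where peaks cluster or are shared by neighbouring genes. With peaks added to promoters so that 50.7% were expected there, 51.3% were found. With CACGTG inserted at 9.46% of summits, it was the single preset motif called and ranked 1 of 2080 6-mers. With 2 of 26 lists enriched in such a random draw of genes, both were called and 0 others.

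Alternatives fixed before the data were examined were the top-ranked regions of each replicate alone in place of the IDR peaks, the stronger 50% of the IDR peaks, merged overlapping peaks, narrower and wider promoter windows, other overlap rules, other flanks and expectations, weaker pooled regions as background, genes with any pooled region as the gene background, circular shifts of the peaks, 1 gene per peak, other locus windows and the ce10 lists. Leaving out peaks within 500 bp of a tRNA gene was added after the data were seen. Coordinates were never converted between builds.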

Results

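NHR-48 belongs to the large nematode family of nuclear hormone receptors, transcription factors that bind DNA through zinc fingers. Its binding was mapped in L4 larvae, the last larval stage before adulthood, with 2 biological replicates of whole animals. On ce11, the lists of peaks with background held 26941 regions for replicate 1, 22704 for replicate 2 and 30000 for both replicates pooled. The IDR list held 3361 peaks, of which 3338 lay on the nuclear chromosomes and 23 on mitochondrial DNA. The IDR peaks were the 3361 pooled regions of highest signal, and 79.0% had the same width, 476 bp. Depth was unknown, because the lists carry no read counts. The questions asked of these data were where NHR-48-GFP bound, whether both replicates showed it, and which genes and sequences lay at the bound regions.

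Both replicates held nearly the whole set of NHR-48 peaks. A region of replicate 1 overlapped 3332 of the 3338 nuclear IDR peaks (99.8%), and a region of replicate 2 overlapped 3318 (99.4%). Both lists overlapped 3312 peaks (99.2%), against a mean of 11.1% and a highest value of 12.8% for random placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The IDR list was derived from the same replicates, so this overlap is not independent of how the list was made. When the 3361 top-ranked regions of each replicate were compared directly, 2715 of 3341 nuclear regions of replicate 1 (81.3%) and 2625 of 3338 of replicate 2 (78.6%) overlapped the other list. Among the IDR peaks, 2669 of 3361 were overlapped by such a top-ranked region in both replicates. The authors' signal at 3312 nuclear peaks had a Spearman rho of 0.777 between replicates, across peaks, which are not independent replicates.

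**Figure D1:**
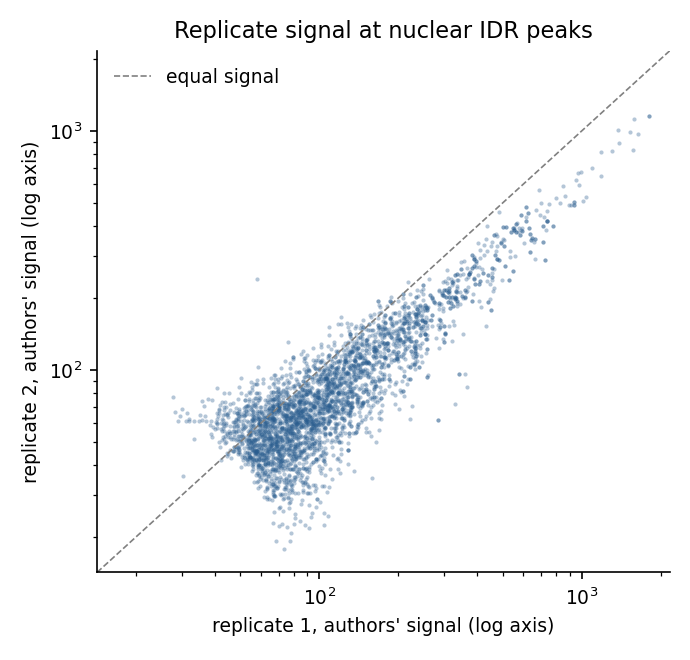
Authors' signal value in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, for the 3312 nuclear IDR peaks with a region in both replicate lists; each point is a peak and the dashed line marks equal values. The points follow a single band, with a Spearman rho of 0.777, that is widest at low signal.

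NHR-48 peaks lay between genes and at promoters more often than chance placement gave. The summits of 1639 of 3338 nuclear peaks (49.1%) fell in a promoter window, against 25.8% for random placements, a 1.90-fold excess (one-sided permutation p = 0.001, the smallest possible). Intergenic sequence held 1954 summits (58.5% against 35.3% expected) and exons of noncoding genes 367 (11% against 3.36%), a 3.27-fold excess. The 5′ UTRs held 117 summits (3.51% against 1.42%). Coding exons held 131 summits (3.92% against 24.3%), a 0.162-fold share, and introns (21.4% against 32.3%) and 3′ UTRs (1.62% against 3.34%) were also below chance. For each of the 6 classes the two-sided permutation p was 0.002, the smallest possible. Weaker pooled regions that overlapped no IDR peak were at promoters in 32.5% of 25416 cases, less often than IDR peaks (odds ratio 2.00, Fisher's exact p = 9.07e-77). Signal did not separate promoter peaks, with a median of 153, from other peaks, with a median of 157 (two-sided permutation p = 0.415). With a window of 2000 bp upstream to 500 bp downstream, the median of promoter peaks minus that of other peaks was -7.54 (two-sided permutation p = 0.0241), and over the 6 alternatives p ran from 0.0241 to 0.944.

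The strongest nuclear peak lay on chromosome V at 6246306 to 6247027, 224 bp upstream of the nearest 5′ end of dmd-7, which encodes a DM-domain transcription factor, and within an exon of a noncoding gene. Its pooled signal was 2955, with 1805 in replicate 1 and 1159 in replicate 2. An intergenic peak at V 11572747 to 11573417 lay in the promoter windows of both H12C20.7 and the nuclear hormone receptor gene nhr-68, with a signal of 2512. Peaks in the promoter windows of D2023.1 (2121), E01G4.3 (1986), ipla-6 (1833), F28C10.3 (1785), the ribosomal protein gene rpl-3 (1631, III 3867302 to 3867838), F21C10.10 (1568), the epsin gene epn-1 (1430), mdl-1, which encodes a Mad-like bHLH protein (1383), tag-340 (1240) and lgg-2, which encodes an LC3-like autophagy protein (1174), followed by pooled signal. Many of the strongest nuclear peaks lay outside all promoter windows, which was noted after the values were seen. Among the 20 strongest these were ranks 2, 3, 5, 6, 7, 12, 14, 15, 17, 19 and 20. Examples are intergenic peaks at II 4089069 to 4089719 (2701) and X 6737371 to 6738175 (2591) and an intronic one in pqn-41 (2255). Such positions were not particular to the strongest peaks, since 1699 of all 3338 nuclear peaks lay outside promoter windows. The 12 nuclear genes with the nearest 5′ end, from dmd-7 to lgg-2, made up the 20 genes named by the preset rule together with 8 mitochondrial genes. In the ranking of 20 nuclear genes, which was added after the values were seen, tatn-1, a tyrosine aminotransferase gene (1115), serp-1.1 (1060), nhr-48 (1023), R02E4.3 (998.7), ZK1290.5 (997), slc-36.4 (982), Y17G9B.5 (964) and nspc-17 (946) came next. Of the peaks of these 20 nuclear genes, 8 were on X, 15 were intergenic, 4 lay in noncoding exons and 1 in an intron. Their summits lay 58 to 787 bp upstream of the nearest 5′ end of the named gene, and each had a region among the top 83 of replicate 1 and the top 94 of replicate 2. The genes were chosen by promoter window, so these positions do not describe the strongest peaks in general.

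The nhr-48 gene itself, at X 15708213 to 15716875 on the plus strand, had a cluster of strong peaks at its 5′ side. Summits lay 3401 bp (signal 948), 1927 bp (1032) and 643 bp (1023) upstream of the first 5′ end and at position 15709795 in an intron (672). In 100 kb around the gene there were 13 IDR peaks, against a median of 4 in windows of this size on X, and 3.16% of the windows held as many. Some were summits of the same or overlapping intervals, and with overlapping peaks merged there were 9, as many as in 8.08% of the windows. The transgene carries a tagged copy of nhr-48, and reads from the transgene and from the chromosomal gene cannot be told apart in these lists. The unc-119 gene (III 10902641 to 10908935), mutated in this strain, had 0 IDR peaks in 100 kb, where the median window on its chromosome held 3. The dafachronic acid receptor gene daf-12 (X 10635908 to 10666875) had 0 promoter peaks but 2 intronic ones, at 10637385 to 10637860 (signal 335) and 10639394 to 10639869 (157). The xenobiotic receptor gene nhr-8 (IV 7710983 to 7714210) had a weak peak in its 5′ UTR (IV 7710825 to 7711300, signal 107.7), which was not among the 3361 top-ranked regions of replicate 2.

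**Figure D2:**
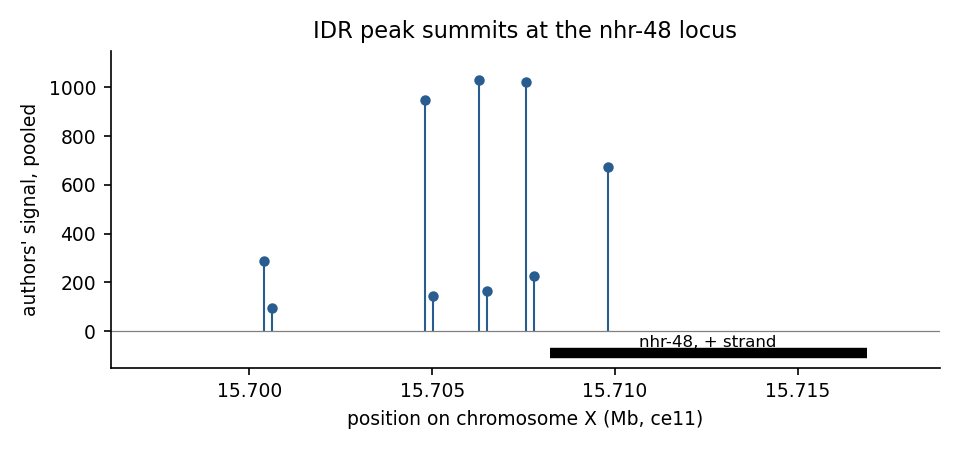
IDR peak summits at the nhr-48 locus on chromosome X (position in Mb, ce11) with the authors' pooled signal on the y axis; the black bar is the annotated gene on the plus strand. The summits with signals of 948, 1032 and 1023 lie upstream of the gene and the one with 672 lies inside it.

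Of the 26 gene lists, ribosomal protein, heterochronic, intestinal, and heat shock and DnaJ genes had NHR-48 peaks more often than other genes. Chemoreceptor, C-type lectin and lysozyme, and neuropeptide genes had them less often. No other tagged protein was analysed here, so whether these differences are particular to NHR-48 was not tested. In total, 1798 of 19973 protein-coding genes (9.0%) had an IDR peak in the promoter window. Among ribosomal protein genes, 39 of 81 did (48.1%, exact 95% interval 36.9 to 59.5), 5.44 times the share of other genes (Fisher's exact test, adjusted p = 6.84e-19), with rpl-3 (1631), rpl-20 (964), rpl-15 (864) and rpl-35 (742) strongest. Intestinal genes had peaks in 13 of 38 cases (34.2%, adjusted Fisher p = 0.000133), among them the protease gene cpr-4 (339), the vitellogenin gene vit-6 (208), cpr-1 (208) and the actin gene act-5 (208). Heat shock and DnaJ genes had them in 15 of 53 (28.3%, adjusted Fisher p = 0.000293), with hsp-16.2 and hsp-16.41 sharing 1 peak (583) and with hsp-90 (565) and hsp-1 (460). The heterochronic genes, which time larval development, had them in 7 of 16 (43.8%, adjusted Fisher p = 0.00113), while 6 more symbols of this list, those of 5 microRNA genes and of the noncoding gene lep-5, matched no protein-coding gene and were not tested. The genes with peaks were kin-20 (314), lin-66 (288), mab-10 (234) and lin-46 (180), and, named after their values were seen, lin-28 (173), lin-14 (130) and alg-2 (109).

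Peaks were less frequent at chemoreceptor genes, with 15 of 1310 (1.15% against 9.55% of other genes, adjusted Fisher p = 1.27e-34). The strongest of these were at srv-1 (508), srh-2 (464), srh-17 (408) and srh-76 (373). C-type lectin and lysozyme genes had 7 of 256 (2.73%, adjusted Fisher p = 0.000509), led by clec-126 (293), ilys-5 (269.8), clec-150 (216) and clec-57 (169). Neuropeptide genes had 2 of 143 (1.40%, adjusted Fisher p = 0.0012), both insulin-like, ins-39 (577) and ins-7 (123). With the 7886 genes that had any pooled region in the promoter window as the background, ribosomal protein genes stayed higher (2.37-fold, adjusted Fisher p = 4.42e-07) and chemoreceptor (0.54-fold, p = 0.0384) and neuropeptide genes (0.208-fold, p = 0.0352) lower, by adjusted Fisher tests. The ratio for chemoreceptor genes had been 0.12 against all genes. The calls ended there for intestinal (1.68-fold, p = 0.148), heat shock (1.78-fold, p = 0.0863), heterochronic (2.05-fold, p = 0.162) and C-type lectin and lysozyme genes (0.652-fold, p = 0.418), all adjusted Fisher values. Over the 10 alternatives, 9 of them adjusted Fisher tests and 1 a permutation test by circular shifts, ribosomal protein and chemoreceptor genes passed in 10, heterochronic genes in 9, intestinal, heat shock and neuropeptide genes in 8, and C-type lectin and lysozyme genes in 7. The highest adjusted p among these Fisher and permutation tests was 0.00649 for ribosomal protein genes, from the smallest permutation p that 1000 shifts can give, 0.22 for neuropeptide and 0.812 for C-type lectin and lysozyme genes, and 0.174 for heat shock genes with 1 gene per peak.

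Nuclear hormone receptor genes themselves had peaks in 36 of 274 cases (13.1%, interval 9.37 to 17.7), 1.47 times the share of other genes, which missed the threshold after adjustment (Fisher p = 0.0193, adjusted p = 0.0559). After nhr-68 (2512) and nhr-48 (1023), the strongest were nhr-58 (544) and nhr-119 (523). This list passed in either replicate's top-ranked regions alone, with an adjusted Fisher p of 0.0307 for replicate 1 and 0.0252 for replicate 2. Over its 10 alternatives, Fisher or permutation tests, the adjusted p ran from 0.00649 to 0.272, and 5 passed. UDP-glucuronosyltransferase genes, which conjugate small molecules, had 12 of 67 (adjusted Fisher p = 0.0559), led by ugt-20 (369), ugt-49 (203), ugt-64 (189) and ugt-62 (172). ABC transporter genes had 10 of 52 (adjusted Fisher p = 0.0614), led by mrp-5 (288), haf-3 (236), abcf-2 (189) and wht-7 (181). Histone genes had 12 of 72 (adjusted Fisher p = 0.0837), with his-61 and his-62 at the same peak (834). The preset list called pan-neuronal had 7 of 37 (adjusted Fisher p = 0.0963), led by tbb-1 (239.9). Whether its members are restricted to neurons was not examined.

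Over their 10 alternatives, UDP-glucuronosyltransferase genes passed in 5, ABC transporter genes in 4, pan-neuronal genes in 3 and histone genes in 2.

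The remaining 14 lists did not pass either. Fatty acid metabolism had 12 of 81 genes with a peak, including nhr-49 (294) and the desaturase gene fat-4 (259), bHLH factors 7 of 38, including hlh-11 (476) and mxl-3 (313), and glutathione S-transferases 7 of 47, including gst-7 (215). The bHLH list was incomplete: mdl-1, named above with a stronger promoter peak (1383), was not counted in it. The vacuolar ATPase had 4 of 21, led by vha-12 (270.1), and the list for steroid hormone synthesis and transport 2 of 14. These were 2 regulatory genes in that list, nhl-2, at the peak also named for tag-340 (1240), and the corepressor gene din-1 (391). Cuticle collagens had 14 of 177, including col-124 (219), cytochrome P450 genes 6 of 76, including cyp-37B1 (208), and molting genes 1 of 28, myrf-1 (258). Homeobox genes had 3 of 92, ceh-38 (303), ceh-99 (195) and ceh-60 (153). Body wall muscle had 4 of 42, hypodermis and seam 3 of 33, pharynx 2 of 27, germline and early embryo 2 of 47, and major sperm proteins 0 of 31 (upper exact bound 11.2%). Adjusted Fisher values for these 14 lists ran from p = 0.129 upward. Over 10 alternatives, fatty acid metabolism passed in 3, among them the window of 2000 bp upstream to 500 bp downstream (2.73-fold, adjusted Fisher p = 4.28e-06), bHLH factors and the vacuolar ATPase in 2, and glutathione S-transferases and cuticle collagens in 1.

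**Figure D3:**
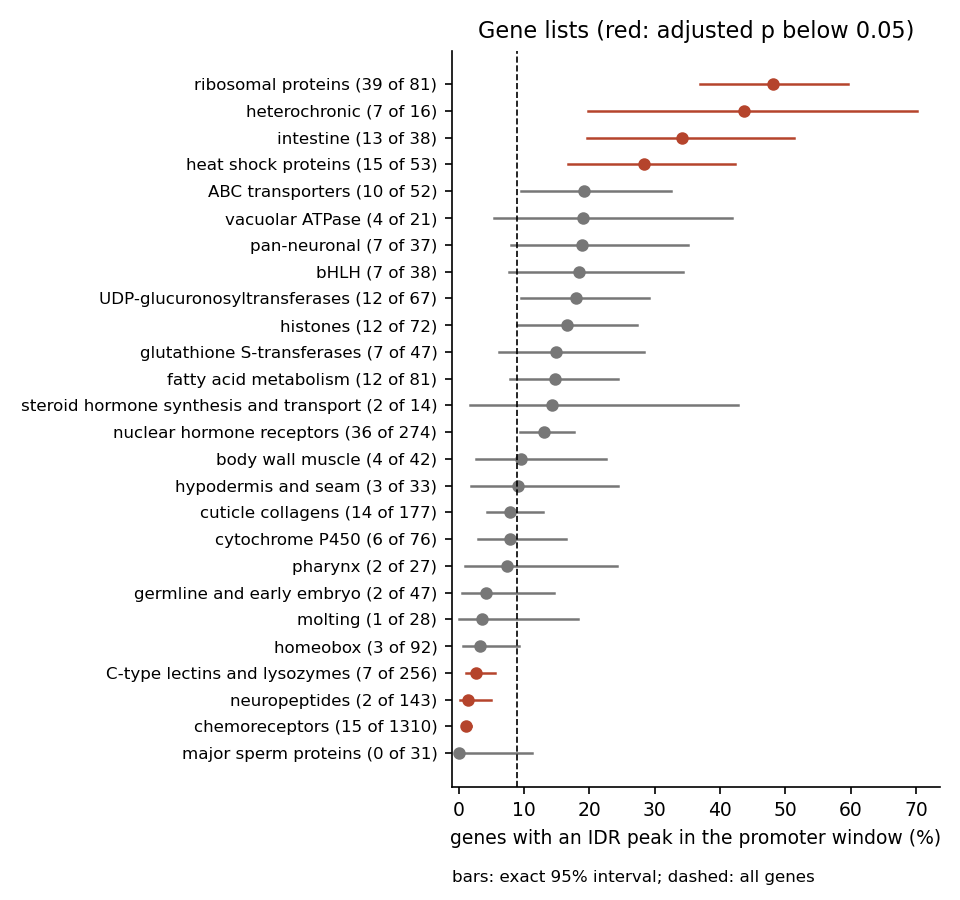
Percent of genes in each of 26 lists with an IDR peak summit in the promoter window (x axis), with exact 95% intervals; labels give the genes with a peak out of all members, red marks adjusted p below 0.05 and the dashed line is the 9.0% of all protein-coding genes. The 4 red lists at the top lie at 28.3% to 48.1%, and the 3 red lists at the bottom left lie at 1.15% to 2.73%.

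The X chromosome held more NHR-48 peaks than its length predicted. It carried 819 of 3338 peaks (24.5%, exact 95% interval 23.1 to 26.0), against 17.7% of nuclear length, a 1.39-fold excess (exact binomial p = 2.48e-23). Weaker pooled regions that overlapped no IDR peak had 21.3% on X, and IDR peaks farther than 500 bp from tRNA genes 22.03% (interval 20.6 to 23.5). X had 46.2 peaks per Mb, and the autosomes from 26.3 on chromosome I to 34.8 on chromosome II. X carries fewer protein-coding genes than its length would give, and against its share of these genes (13.7%) the excess was 1.79-fold (exact binomial p = 6.79e-63). On the autosomes, 1164 of 2519 peaks (46.2%, interval 44.2 to 48.2) lay in the central 33.3% of the chromosome (exact binomial p = 1.07e-40), with the highest share on chromosome I (54.7%) and the lowest on chromosome III (41.9%). The share of protein-coding genes in these centres was 38.1%, and the excess over it was 1.21-fold (exact binomial p = 1.17e-16). On X the central share was 33.9% (interval 30.7 to 37.3), which did not differ from 33.3% (exact binomial p = 0.711); the difference between X and the autosomes was not tested.

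**Figure D4:**
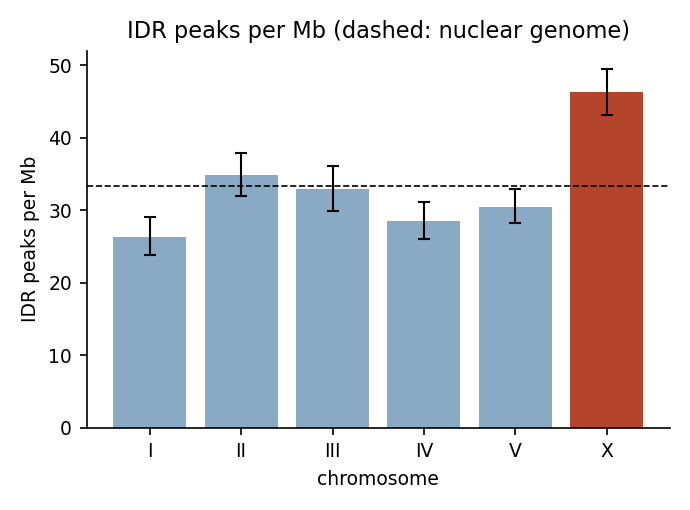
IDR peaks per Mb (y axis) on each nuclear chromosome (x axis), ce11; error bars are exact 95% Poisson intervals of the counts and the dashed line is the nuclear mean. X stands at 46.2 peaks per Mb, above the 26.3 to 34.8 of the autosomes.

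GAGA, E-box and GATA sequences were concentrated at NHR-48 summits. Of the core sequences of nuclear receptors, AGTGCA was too, at a lower ratio, while the others were not in the main test. GAGAGA occurred in 21.9% of summit windows and 6.65% of flank windows (3.29-fold, exact McNemar test, adjusted p = 6.22e-73). CACGTG, an E-box bound by bHLH factors, occurred in 7.91% against 1.71% (4.63-fold, exact adjusted p = 2.55e-34), and TGATAA, bound by GATA factors, in 20.3% against 10.4% (1.96-fold, exact adjusted p = 1.17e-29). Of the nuclear receptor sequences, AGTGCA was in 6.14% against 3.83% (1.60-fold, exact adjusted p = 3.14e-05) and AGTTCA was less frequent at summits, 5.27% against 7.22% (exact adjusted p = 0.00225). AGGTCA was in 3.45% against 2.76% (exact adjusted p = 0.15), and a pair of AGKKCA sequences within 25 bp in 0.33% against 0.389% (exact adjusted p = 0.839). TGACTCA (0.839% against 1.05%, exact adjusted p = 0.506) and ATTGCAT (1.5% against 2.10%, exact adjusted p = 0.12) also missed the threshold. Summit windows held 43.8% G and C against 35.4% in flanks, and 6-mers with the same G and C number as AGTGCA had a median ratio of 1.16, with AGTGCA at percentile 86.4, those like TGATAA 0.634 and those like CACGTG 1.5. For GAGAGA and AGGTCA this median was also 1.16, and AGGTCA, with a ratio of 1.25, was at percentile 60.2. For AGTTCA, with a ratio of 0.73, the median was 0.88 and the percentile 25.6, so a lower share at summits was common among sequences of its composition. With replicate 1 alone the ratio of CACGTG was 3.06, and with flanks nearer the summit the ratios were 2.84 for CACGTG, 1.70 for GAGAGA and 1.37 for TGATAA, all still past the threshold. The call for AGTTCA ended with replicate 2 alone (exact adjusted p = 0.061), with nearer flanks (0.822-fold, exact adjusted p = 0.101) and against weaker pooled regions (Fisher adjusted p = 0.234). AGGTCA passed against weaker pooled regions (3.45% against 2.59%, Fisher adjusted p = 0.0133) and with replicate 1 alone (1.41-fold, exact adjusted p = 0.032). Over 8 alternatives, the exact McNemar or Fisher adjusted p ran from 0.000183 to 0.234 for AGTTCA and from 0.0133 to 0.776 for AGGTCA.

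Across all 6-mers, 688 were more frequent at summits and 403 in flanks. Of the former, 51 exceeded the median of 6-mers of the same composition by more than a ratio of 2. By p value, the leading ones after GAGAGA were ACGCAG (11.6% against 1.68%, 6.91-fold), AGAGAC (16% against 3.89%), AGAGAG (18.6% against 5.75%), GACGCA (11.5% against 2.04%) and CGCAGA (11.2% against 2.07%). GATAAG, an extended GATA site, was in 13.2% against 4.34%. Whether any of these motifs and 6-mers is particular to NHR-48 was not tested either, as peaks of other proteins were not analysed.

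**Figure D5:**
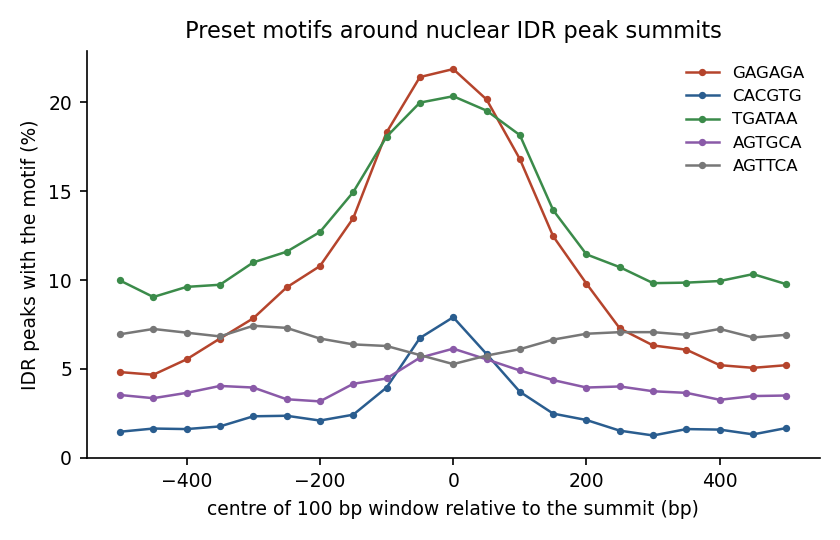
Percent of the 3338 nuclear IDR peaks (y axis) with each motif, on either strand, in 100 bp windows centred at the distances from the summit on the x axis (bp). GAGAGA, TGATAA, CACGTG and AGTGCA rise to 21.9%, 20.3%, 7.91% and 6.14% at the summit, and AGTTCA dips to 5.27%.

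The ce10 lists gave nearly the same numbers. They held 3376 IDR peaks, 26885 regions for replicate 1 and 22480 for replicate 2. The median width of the IDR peaks was 476 bp on both builds. X carried 820 of the ce10 IDR peaks (24.5% of nuclear ones), and mitochondrial DNA 23.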

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

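Both tests of the mitochondrial peaks were chosen after the peaks had been seen. The IDR list held 23 peaks on mitochondrial DNA, data outside the nuclear comparisons, where a count of 0 would allow 3. They lay in 6 distinct intervals with signals of 892 to 7714 and a median of 2815, 18.2 times the nuclear median of 155, and took 14 of the 20 highest signals in the list. By the preset rule, 8 mitochondrial genes were among the 20 named, including COX3 (7048) and ND1 (3492), which encode subunits of the respiratory chain.

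Regions in both replicate lists overlapped 22 of the 23 peaks, but this says nothing about a source in 1 replicate, since the IDR list is made from both lists and 99.2% of its nuclear peaks overlapped both. The peaks covered 87.6% of the mitochondrial DNA, against 1.40% of the nuclear genome, which is what reads spread over the whole molecule would give, as many DNA copies per cell could produce. How far the control library removed such reads stays open, because it was not analysed here, and no biological explanation was tested.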

How the results depend on the processing

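Leaving out peaks near tRNA genes was chosen after the data were seen; the other alternatives were fixed before. Of 884 recomputed values, 770 were judged unchanged, and 400 of these were checks of whether a named gene kept its promoter peak. A tested result had to keep its direction and side of the threshold. A count had to stay within 1.5-fold, and other values within the 95% interval of the main value. Every promoter, class, X and centre share and every 6-mer count was unchanged by these rules, under each alternative run for them. Sizes could still move. With the stronger 50% of peaks, the 3′ UTR share went from 0.484-fold to 0.252-fold, and 6-mers higher at summits from 688 to 564. Overlap of equally long top lists was 82.8% for 1000 regions and 73.9% for 6722, and the Spearman rho was 0.716 with nearest summits and 0.697 without the strongest 10% of peaks. Lists that passed as higher numbered 4 in the main test, 5 to 9 with 1 replicate, 8 with the wide window, 1 among genes with a pooled region, 14 with circular shifts, which also count the general preference for promoters, and 7 with 1 gene per peak. Lists that passed as lower numbered 3, but 2 among genes with a pooled region, 1 with the stronger 50% of peaks and 1 with circular shifts. Motifs lower at summits numbered 1, but 0 to 1 with 1 replicate, 0 with nearer flanks and 0 against weaker regions. The median signal of promoter peaks was -0.599 to 0.366 relative to others with 1 replicate, 0.687 with the stronger 50% of peaks and -7.54 with the wide window. The percentile of the nhr-48 window was 96.8, with 94.2 to 96.7 for 1 replicate, 91.9 after merging, 98.7 for 40 kb and 92.4 for 200 kb. This percentile is the share of windows with fewer peaks, so it is 0 for any window without peaks, as at unc-119. With 200 kb the unc-119 window held 5 peaks and its percentile was 36.05. In the pooled list with background, the percentiles for 100 kb were 78.7 for nhr-48 and 32.3 for unc-119. Lists and motifs without a call crossed a ratio of 1: with 1 replicate, molting (0.394 to 1.23), cuticle collagens (0.713 to 1.19), muscle (0.526 to 1.10), TGACTCA (0.732 to 1.14) and the AGKKCA pair (0.917 to 1.55); with the stronger 50%, muscle (0.516) and pan-neuronal (0.586); without peaks near tRNA genes, hypodermis (0.699); with the narrow window, muscle (0.713), hypodermis (0.454) and pharynx (1.11); with the wide window, molting (1.16) and muscle (0.774); among genes with a pooled region, fatty acid metabolism (0.993), muscle (0.649) and hypodermis (0.731); with circular shifts, cuticle collagens (2.13, now past the threshold), cytochrome P450 (2.17), pharynx (1.63) and germline (1.02); with 1 gene per peak, cuticle collagens (1.01), steroid hormones (0.98), hypodermis (0.831) and pharynx (1.02); with farther flanks, TGACTCA (1.33) and the pair (1.10). The cause of these shifts was not tested, except that a shifted expectation or a smaller gene background is part of its alternative. Of 424 checks of named promoter peaks, 24 lost the peak, most with the stronger 50% of peaks, where fewer are counted. Depth was unknown, so its limits could not be given.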

Other observations

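The gene groups, the 8-base words, the removal of peaks near tRNA genes and both tests of X against weaker pooled regions were chosen after the data were seen. Several classes of noncoding genes carried peaks often. With a window of 500 bp upstream to 200 bp downstream of the 5′ end, 269 of 612 tRNA genes (44%, exact 95% interval 40 to 48) held an IDR summit, against a mean of 15 and a highest value of 29 in 1000 circular shifts of the peaks. The same held for 94 of 346 snoRNA genes (mean of shifts 7.24), 28 of 129 snRNA genes (2.69) and 29 of 261 miRNA genes (6), each with a two-sided permutation p of 0.002, the smallest possible. Protein-coding genes in the same window, 1240 of 19973, were 2.88-fold above shifts, beside 4.83-fold for miRNA genes and 17.9-fold for tRNA genes. Genes of piRNAs, with 124 of 15363 against 291 by shifts (permutation p = 0.002), and pseudogenes, with 27 of 2128 against 44.4 (adjusted permutation p = 0.0178), went the other way. Of 276 tRNA genes on X, 156 had a peak (56.5%), against 113 of 336 on autosomes (33.6%, Fisher's exact p = 1.49e-08). Neighbouring tRNA genes can share a peak, while this test treats genes as independent, and copy number was not taken into account. The peaks near tRNA genes were not the strongest, with a median signal of 148 against 156 elsewhere.

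Among 175 families of genes with a shared symbol and at least 10 members, 5 were higher and 8 lower after adjustment. Beyond ribosomal proteins and hsp genes, the lin genes had peaks in 13 of 47 (27.7%, adjusted Fisher p = 0.00405), led by lin-54 (446, the same signal as at rpl-12), lin-59 (369), lin-9 (360) and lin-53 (320) and including heterochronic genes named above, and the bZIP genes named zip had 6 of 12 (adjusted Fisher p = 0.00529), led by zip-2 (302). F-box genes named fbxa were low, with 3 of 170 (adjusted Fisher p = 0.0041), as were nlp neuropeptide genes, with 0 of 71 (adjusted Fisher p = 0.0384). ACGCAG and GACGCA, 2 of the leading 6-mers, lie in AGACGCAG, which was in 7.28% of summit windows and 0.509% of flanks. Near tRNA genes it was in 0.405% of summit windows and elsewhere in 7.83%. The word was picked from 400 frequent at summits, so its ratio is not free of that choice.

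Peaks at tRNA genes may come from technical sources. Reads shared between identical copies were tested on 140 tRNA genes whose full sequence occurs once in the genome. Of these, 42 had a peak, above the highest of the shifts, 10, which identical copies alone were not predicted to give. The test cannot exclude shared reads, because a copy that differs by few bases counts as another sequence. A window can also hold the summit at a neighbouring tRNA gene. Genes with copies did have peaks more often (48.1% against 30%, Fisher's exact p = 0.000149, with genes treated as independent), so shared reads stay open as a source. Overlap with promoters of protein-coding genes was argued against as the whole cause, since 169 of 394 tRNA genes outside promoter windows had a peak, with a highest shift of 23. Signal that any tagged protein would give at open, highly transcribed genes stays open and was not tested, because no other protein was analysed here, and no biological explanation was tested.

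Peaks near tRNA genes, 138 of 247 of which lay on X, could account for a part of the excess of peaks on X: without them the X share was 22.03% (interval 20.6 to 23.5), still above 17.7%. Extra copies of DNA around nhr-48 from the transgene were argued against as the cause, since the share was 24.2% without 100 kb around the gene. Weaker pooled regions that overlapped no IDR peak were on X in 21.3% of cases, above the share of length but below the interval of all IDR peaks (23.1 to 26.0). With regions near tRNA genes left out of both, the weaker regions had 21.2%, inside the interval of the IDR peaks (20.6 to 23.5). So tRNA genes and an X share common to all regions may together account for the excess. That common share was itself uncertain. In the lists with background, strong regions included, X held 19.9% of nuclear regions for replicate 1 and 23.7% for replicate 2. No biological explanation was tested.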
